A study of Homo sapiens with 12 samples.

How the data were processed

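Primary human aortic endothelial cells in EGM-2 medium were kept for 24 hours at 21% oxygen (normoxia) or 1% oxygen (hypoxia), per the labels' protocols. Each oxygen level has 3 RNA-seq libraries (TruSeq) and 3 ATAC-seq libraries (Nextera, a transposase assay that marks open chromatin), and the libraries of each assay were pooled on 1 lane, per the labels. The labels do not say whether the libraries of a group come from separate cultures or donors, so the p-values measure only the spread between these libraries. Replicate numbers are not stated to pair samples, and the gene-wise deviations of equally numbered normoxia and hypoxia libraries had correlations of 0.0119, -0.0415 and 0.0133, so the main tests are unpaired.

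For RNA, each deposited table holds RSEM values of 1 library for 208900 transcripts: the expected count (an estimated count without normalization), TPM, FPKM (not used in tests), the percent of the gene's TPM in each isoform, and the effective length in bases, per the file headers. Alignment with STAR and quantification with RSEM are named without versions in the submitters' processing notes. The notes also name DESeq2, DiffBind, edgeR and HOMER 4.11.1, whose output is not used here. For ATAC, each deposited table is a MACS2 narrowPeak list of 1 library, with the summit's fold over the caller's background (a ratio), the -log10 p and -log10 q of each peak, a score derived from the q-value and the summit position, per the file headers and format. The submitters' processing notes name BWA 0.7.17-r1188, SAMtools 1.10 and MACS2 2.1.0. They give the builds hs37d5 and hg19, while peak names in the deposited lists say hg38 and peaks lie beyond the hg19 ends of chromosomes 3, 5, 17 and 20, so ATAC coordinates are given as hg38 (GRCh38), 1-based. Peak heights were ranked or filtered within a list, and compared between lists only at regions open in all 6, where the fold also depends on background coverage.

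Expected counts were summed per gene and rounded (38.9% of the values were not whole). Of 60843 genes, 477 on chromosome Y or XIST were left out because the cells come from human donors, and 55900 of the 60366 kept had a symbol, holding 99.73% of counts. PECAM1 and the 13 mitochondrially encoded protein genes are not analysed here. Total counts were 58684796, 45217893 and 47179135 in the normoxia libraries and 42358561, 58880391 and 70235869 in the hypoxia libraries. Genes were filtered with filterByExpr, scaled with TMM and tested with the edgeR 4.0.16 quasi-likelihood test (limma 3.58.1, R 4.3.3), at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-normalised CPM, mean ± SD, n = 3. The log2 fold changes are hypoxia against normoxia. Their standard error (SE) was derived from the edgeR test, as the absolute unshrunken coefficient over the square root of the F statistic.

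The lists of genes, comparisons, tests, alternatives and naming rule were fixed before the data were examined. The 26 lists cover glycolysis and lactate, core hypoxia targets, the HIF pathway, 2-oxoglutarate-dependent chromatin dioxygenases, collagen modification, basement membrane and matrix, endothelial identity, angiogenesis with tip-cell and Notch genes, cell cycle, cholesterol synthesis, ER stress, nuclear OXPHOS genes, mitochondrially encoded genes, TCA cycle, inflammation, interferon response, TGF-beta and EndMT (endothelial-to-mesenchymal transition), p53 targets, immediate early genes, autophagy and lysosome, and markers of smooth muscle, fibroblasts, pericytes, leukocytes, epithelium and lymphatic endothelium. Lists were tested with camera at a preset correlation of 0.01, adjusted together, then with the correlation estimated from the residuals, and with fry. The text names HIF subunits and regulators whatever their result, the 10 genes that rose most and the 10 that fell most (protein-coding, mean CPM of at least 5, groups not overlapping), up to 4 members per list with the largest change, the 5 isoform genes with the smallest p and a shift of at least 20 percentage points, regions at EPAS1, and the 5 regions per class with the largest minimum fold. Some items that the rule picks are not used here. Members named outside this rule were chosen after their values were seen.

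Isoform usage was tested with edgeR diffSpliceDGE on rounded expected counts in 11099 genes with 2 or more transcripts past the filter, with a Simes p per gene. The 6 peak lists were merged into regions where peaks overlap by at least 1 base. A region is hypoxia-specific if it is open in all 3 hypoxia lists and in 0 normoxia lists, and normoxia-specific in the reverse case. Background coverage was recovered from each peak's fold and p, and pileups were thinned to the lowest background coverage, an alternative chosen after the data were seen. Gene spans came from the RefSeq annotation of GRCh38.p14, which gives no strand, exon or transcription start here, so distances are to the nearest span and gene ends stand in for starts. A total of 14495 of the 16332 genes tested (88.8%) had a span. Genes nearest to a specific region and within 50 kb were tested with camera and Fisher's exact test. Motif counts were not run, because no genome sequence was at hand. Differences between single values used exact permutation tests, two-sided, which cannot give a p under 0.1 with 3 against 3. Intervals on shares are exact (Clopper-Pearson, 95%) and cover counting error only.

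The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size only, no filter, a CPM of at least 1 in 3 samples, limma-trend on log2 TPM with 1 or 0.1 added, counts scaled from TPM, a replicate block, leaving out each library, stricter q-values, the 50000 strongest peaks per list, trimmed peaks, occupancy in at least 2 lists and other distances. The RNA test was checked on simulated counts with 200 changed genes. It recovered 26 of 50 genes (52%) at a fold of 1.25 and 33 (66%) at 1.5. It recovered 37 of 50 (74%) at 2 and 47 (94%) at 4, with 21 false calls among 16042 genes. Far more genes changed in the data, and adjusted p depends on that number, so these percentages do not give the recovery there. The isoform test recovered 100 of 100 simulated changes with 11 false calls among 10981 genes. In both checks the share of false calls among all calls was above the adjusted p threshold of 0.05. Whether the calls in the data hold such a share was not tested. The simulated isoform changes were full swaps of the 2 most abundant isoforms, with a single fixed spread and no error in assigning reads to isoforms. They do not show how the test handles smaller shifts or the spread of these libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.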

Results

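RNA-seq and ATAC-seq were made from primary human aortic endothelial cells, the cells that line the aorta, after 24 hours at 21% or 1% oxygen, with 3 libraries per oxygen level and assay. RNA libraries held 42358561 to 70235869 expected counts, and ATAC peak lists held 66502 to 105016 peaks. The series concerns a hypoxia-sensitive enhancer of EPAS1, the gene for HIF-2 alpha, so the comparisons ask how transcripts and open chromatin differ between the oxygen levels, at EPAS1 and elsewhere.

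In hypoxia, transcripts of EPAS1 and HIF1A, the alpha subunits of the hypoxia-inducible factors, were lower, while EGLN1 and EGLN3, prolyl hydroxylases that mark these subunits for degradation, were higher. EPAS1 (ENSG00000116016.13_2) fell from 803 ± 21.4 to 569 ± 18.2 CPM (SD, n = 3; log2 fold change -0.50, SE 0.03, edgeR adjusted p = 6.2e-07). HIF1A fell from 176 to 136 CPM (log2 fold change -0.37). EGLN1 rose from 54.8 ± 1.38 to 194 ± 0.776 CPM, a log2 fold change of 1.83 (SE 0.03, edgeR adjusted p = 9.3e-11). EGLN3 rose from 0.0236 to 7.77 CPM, with 1 or 2 counts in each normoxia library and 282 to 502 in each hypoxia library. HIF3A, which encodes a further alpha subunit, rose from 8.58 to 13.8 CPM with TMM scaling, and its call was lost on log2(TPM + 1), where its log2 fold change was 0.17. VHL, which encodes the ubiquitin ligase subunit that binds hydroxylated HIF, fell by 0.34 on the log2 scale, and EGLN2 fell by 0.19. ARNT, the beta subunit, had a log2 fold change of -0.03 (edgeR adjusted p = 0.423), and HIF1AN, the asparagine hydroxylase of HIF, one of -0.02 (edgeR adjusted p = 0.601). Both passed with library-size scaling, at -0.30 and -0.28.

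**Figure D1:**
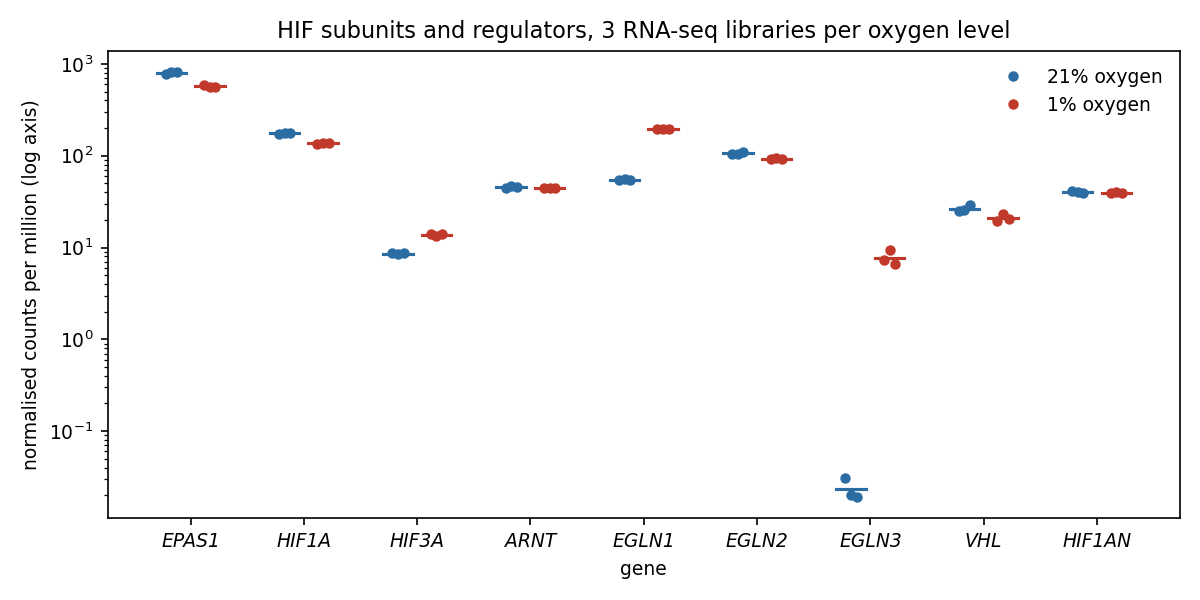
TMM-normalised CPM (log axis) of HIF subunits and regulators in each RNA-seq library at 21% (blue) and 1% oxygen (red); points are libraries and bars are means of 3. EPAS1 lies between 778.57 and 817.4 in normoxia and between 555.06 and 589.73 in hypoxia.

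Among protein-coding genes with a mean CPM of at least 5, ANGPTL4, which encodes an inhibitor of lipoprotein lipase, rose most in hypoxia. EGLN3, below that level, rose by more. ANGPTL4 rose from 23.5 ± 0.717 to 538 ± 23.6 CPM, a log2 fold change of 4.52 (SE 0.04, n = 3, edgeR adjusted p = 5.3e-12). INHBA, an activin subunit, rose by a log2 fold change of 4.17, ANKRD37 by 3.57, and SLC2A1, the glucose transporter GLUT1, by 3.33. GDF6, a BMP-family ligand, rose by 3.30, the adenylate kinase AK4 by 3.08, ADSS1 by 3.06, and the vasodilator peptide gene ADM by 2.97. APLN, the ligand of the apelin receptor, rose from 372 to 2662 CPM, and PTGIS, prostacyclin synthase, from 15.8 to 111 CPM. Of the genes at that level, the one that fell most was GJA4, the gap junction protein connexin 37, from 24.0 ± 0.539 to 1.11 ± 0.252 CPM (log2 fold change -4.45, SE 0.10, n = 3, edgeR adjusted p = 7.5e-10). The water channel gene AQP1 had a log2 fold change of -3.16, the Notch modifier LFNG -2.18, and the death ligand gene TNFSF10 -1.98. BTN3A1 (-1.95), the fatty acid elongase ELOVL6 (-1.95), the transporter gene ABCG2 (-1.88), the DNA polymerase gene POLQ (-1.86) and DHH (-1.83) were also among the genes that fell most. In all, 10110 of 16332 genes tested changed, 5055 higher and 5055 lower, and 641 of the higher and 799 of the lower ones by at least 2-fold. Asking glmTreat for a fold beyond 2 left 402 genes, 261 of them higher. The equal number in each direction depends on scaling: with library size only, 2259 genes were higher and 9073 lower, and the median gene moved by -0.264 on the log2 scale relative to TMM.

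Glycolysis and the core hypoxia targets were the gene lists that rose most uniformly. Of 22 glycolysis and lactate genes, 21 rose and 1 fell. At the top by log2 fold change were SLC2A1, SLC2A3 (1.75), PDK1 (1.65), a kinase that inhibits pyruvate dehydrogenase, and ALDOA (aldolase, 1.63). The exception was PFKM (-0.13). The list's camera adjusted p was 4.18e-55, and 0.0402 with an estimated correlation. Of 27 core hypoxia genes tested, 26 rose over all genes tested and 27 adjusted over the list alone, including MIR210HG, host of the hypoxia-induced microRNA 210, at 4.18. The remaining gene over all genes tested was BHLHE41, at a log2 fold change of 0.20 (edgeR adjusted p = 0.0513). The list's camera adjusted p was 1.19e-75, and 0.0145 with an estimated correlation. In the HIF pathway list, 8 of 15 rose, among them the HIF-restraining genes CITED2 (1.07) and CITED4 (0.82), and 5 fell, EPAS1, HIF1A, VHL, EGLN2 and CUL2. Its camera adjusted p of 0.00723 became p = 0.569 with an estimated correlation, and its median flips from 0.21 to -0.06 with library-size scaling.

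The lists of collagen modification, matrix, angiogenesis and TGF-beta genes passed camera's test at the preset correlation and not at an estimated one, and each held both raised and lowered genes. Of 13 collagen modification genes, 10 rose, with the crosslinking oxidases LOX (2.27) and LOXL2 (1.45), the lysyl hydroxylase PLOD2 (1.55) and the prolyl hydroxylase P4HA1 (1.39), and P4HA3 and SERPINH1 fell. The camera adjusted p was 8.11e-10, with p = 0.221 at an estimated correlation. Of 20 basement membrane and matrix genes, 13 rose, including THBS1 (1.09), COL5A1 (0.56) and COL1A2 (0.49), and LAMA5 (-0.79) and FBN1 fell. That list had a camera adjusted p of 0.0299, and p = 0.713 with an estimated correlation. Its median flips from 0.23 to -0.03 with library-size scaling, where 7 rose and 8 fell. Of 24 angiogenesis, tip-cell and Notch genes, 11 rose, with APLN, CXCR4 (1.89), PDGFB (1.70) and ANGPT2 (1.59), and 9 fell, for a camera adjusted p of 1.34e-06 and p = 0.221 with an estimated correlation. Its median of 0.02 flips to -0.24 with library-size scaling. Of 20 TGF-beta and EndMT genes, 12 rose and 6 fell, with the ligand gene TGFB2 at 2.40, TGFBI at 1.82, N-cadherin CDH2 at 1.78 and CCN2 at 1.51. The list's camera adjusted p was 1.34e-06, with p = 0.293 at an estimated correlation.

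Cell-cycle genes fell together: all 28 passed in that direction, including the proliferation marker MKI67 (-1.48), the replication genes CDC6 (-1.32) and CDC45 (-1.11) and CENPF (-1.05). The camera adjusted p was 4.57e-07, with p = 0.713 at an estimated correlation, for genes whose estimated correlation with one another was 0.913. Of 23 cholesterol synthesis genes, 12 fell, led by HMGCS1 (-0.67), STARD4 (-0.49), HSD17B7 (-0.44) and IDI1 (-0.41), and FDPS and SREBF2 rose (0 rose and 22 fell with library-size scaling), with a camera adjusted p of 0.0467 and p = 0.783 at an estimated correlation. Of 21 interferon response genes, 9 fell, with the signal transducer STAT2 (-1.14), OAS3 (-1.01), OAS1 (-0.94) and IFI44 (-0.77), and MX1 and IFI27 rose. Its camera adjusted p was 0.0453, with p = 0.783 at an estimated correlation, and with library-size scaling 2 rose and 16 fell. Of 17 autophagy and lysosome genes, 13 rose, with CTSB (0.47), WIPI1 (0.47), MAP1LC3B (0.44) and CTSD (0.39), and CTSL fell. The camera adjusted p was 0.0467, with p = 0.722 at an estimated correlation. The median flips from 0.23 to -0.04 with library-size scaling, where 4 rose and 6 fell.

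Lists whose camera test did not pass still held members that changed, as did genes at large. Of all 16332 genes tested 10110 passed, 5055 higher and 5055 lower, so counts near that share do not set a list apart. Among 21 endothelial identity genes, 7 rose and 7 fell (camera adjusted p = 0.694), and with library-size scaling 5 rose and 13 fell: NOS3, endothelial nitric oxide synthase, fell from 274 to 93.0 CPM (log2 fold change -1.56), the flow-responsive factor KLF2 had -1.03, the tight junction gene CLDN5 fell from 108 to 54.3 CPM, and ROBO4 rose by 0.87. Among 18 inflammation genes, 10 rose and 2 fell (camera adjusted p = 0.127), with the adhesion molecules ICAM1 (2.00) and SELE (1.75), CX3CL1 (1.45) and CSF3 (-1.92), and the median flips sign with library-size scaling. Among 36 nuclear OXPHOS genes, 22 rose and 6 fell (camera adjusted p = 0.118), with COX6C (0.45), COX4I1 (0.44), NDUFB10 (0.35) and NDUFB3 (-0.34), and with library-size scaling 3 rose and 22 fell. Among 17 TCA cycle genes, 6 rose and 8 fell (camera adjusted p = 0.993), with IDH2 at 0.83, OGDH at -0.58, IDH3B at 0.43 and MDH2 at 0.43. The list's median of 0.01 and its camera direction, down, differ in sign, and the median flips with library-size scaling, where 3 rose and 12 fell. Among 20 ER stress genes, 9 rose and 9 fell (camera adjusted p = 0.823, direction down against a positive median that flips with library-size scaling), with CHAC1 (1.16), ATF3 (0.80), PPP1R15A (0.67) and ATF4 (0.60). Among 18 dioxygenases of chromatin, 6 rose and 5 fell (camera adjusted p = 0.625, with a median that flips with library-size scaling, where 2 rose and 11 fell), with the histone demethylases KDM3A (0.90), KDM4B (0.65) and KDM5B (0.36, lost with library-size scaling) and the DNA demethylase TET2 (-0.34). Among 17 p53 targets, 4 rose and 9 fell (camera adjusted p = 0.344; 2 and 13 with library-size scaling), with SESN1 (-0.67), TNFRSF10B (0.63), FDXR (-0.60) and FAS (-0.52). Among 16 immediate early genes, 5 rose and 8 fell (camera adjusted p = 0.344, direction up against a negative median), with DUSP1 (1.43), IER3 (1.32), JUN (1.01) and EGR3 (-2.98). EGR3 was too low for the filter of a CPM of at least 1, and its value ranged from -4.93 to -2.28 without 1 library. Adjusted over the list alone, 3 collagen modification genes, 7 TGF-beta and EndMT genes and 8 interferon response genes fell and 10 ER stress genes rose, and the other lists with a camera test, apart from the core hypoxia genes, had the counts given over all genes tested. None of the mitochondrially encoded genes was tested.

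Further gene families, drawn up after the data were seen, held some of the most uniform changes. All 73 cytosolic ribosomal protein genes rose, among them RPLP0 (0.58), RPS2 (0.56) and RPL3 (0.55), with a median of 0.43 that was 0.17 with library-size scaling, where 66 passed (camera adjusted p = 7.02e-27, and p = 0.226 with an estimated correlation). Of 27 actin cytoskeleton genes, 25 rose and 1 fell, including TPM1 (1.28), MYL9 (1.22) and ACTB (0.52), with a camera adjusted p of 2.19e-20 and p = 0.226 with an estimated correlation. Of 26 homologous recombination and Fanconi anaemia genes, 22 fell, including BRCA1 (-1.35), BRCA2 (-1.16) and FANCD2 (-1.01), and the family also holds POLQ. Of 16 mismatch and base repair genes, 13 fell and 2 rose (camera adjusted p = 0.0124, and p = 0.226 with an estimated correlation). Of 20 BMP and activin genes, 11 rose and 8 fell, with BMP4 at 1.12, SMAD7 at 1.14 and ID1 at -1.40, and the family also holds GDF6 and INHBA. Of 17 NRF2 targets, 9 fell and 3 rose, and all 17 fell with library-size scaling, with HMOX1, heme oxygenase 1, at -1.55 and NQO1 at -1.10 (camera adjusted p = 0.000219, and p = 0.226 with an estimated correlation). Of 8 prostaglandin genes, 5 rose, with PTGS1 at 1.21, and 2 fell, and the median flips with library-size scaling. That family also holds PTGIS. No set p is given for the families that hold POLQ, GDF6, INHBA or PTGIS, which were already among the genes with the largest changes. The set p-values of the remaining families only describe these data, because those families too were drawn up after the data were seen. The members named here were chosen after their values were seen. The other 7 of the 14 families did not pass, with camera adjusted p from 0.0849 for the spliceosome to 0.562 for the mitochondrial ribosome.

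Markers of other cell types showed no common direction. Of 5 smooth muscle markers tested, TAGLN rose by a log2 fold change of 1.78, SMTN (-0.52) and ACTA2 (-0.48) fell, and 2 did not pass (camera adjusted p = 0.767, direction up against a negative median). Of 3 fibroblast markers, COL1A2 and FAP rose (camera adjusted p = 0.682), FAP from 0.418 to 0.787 CPM, a call lost with library-size scaling, both TPM settings, counts scaled from TPM and without either replicate 2. Of 3 pericyte markers, PDGFRB fell from 0.600 to 0.219 CPM (camera adjusted p = 0.767, and a median that flips with library-size scaling). The single leukocyte marker tested, CD68, rose by 0.29, and its direction flips on log2(TPM + 1). Of 3 epithelial markers, KRT8 (0.38) and KRT18 (0.15) rose and KRT19 (-0.25) fell (camera adjusted p = 0.742), and KRT18, at -0.11, and the list's median flip with library-size scaling. Of 4 lymphatic endothelial markers, LYVE1 (-0.89), PROX1 (-0.48) and FLT4 (-0.32) fell and RELN (0.38, lost with library-size scaling) rose (camera adjusted p = 0.344).

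Isoform usage moved in a smaller set of genes, among them PCSK7, a proprotein convertase, and CFDP1. In PCSK7, transcript ENST00000320934.7_1 went from 13.3% ± 0.629 to 43.2% ± 3.05 of the gene's TPM (SD, n = 3, edgeR adjusted p = 2.1e-06). In CFDP1, ENST00000283882.3_1 went from 81.0% to 48.2% and the shorter ENST00000570103.5_1 from 9.36% to 46.6% (edgeR adjusted p = 2.6e-05). In RGS3, a regulator of G-protein signalling, ENST00000620489.1_2 went from 46.6% to 69.9%. In PTPA, ENST00000393370.6_1 went from 33.5% to 6.60%, and in FRMD3, ENST00000621208.4_1 went from 0% to 23.8% ± 14.3. Of 11099 genes tested, 362 changed, 36 of them with a shift of at least 20 points in some transcript. The count was 214 with transcripts of at least 10% of the gene, 1037 with a gene-level F test and 211 with a replicate block. Without 1 library it was 314 to 385, of which 193 to 213 were among the 362.

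The hypoxia ATAC lists held fewer peaks than the normoxia lists. The normoxia lists held 102234, 100118 and 105016 peaks and the hypoxia lists 69453, 66502 and 83629, a mean of 102456 ± 2457 against 73195 ± 9156 (SD, n = 3), or 28.6% fewer. Peaks covered 58.8 ± 0.723 Mb in normoxia and 35.1 ± 5.81 Mb in hypoxia. The exact permutation p was 0.1 for both (n = 3), the smallest this design allows. The background coverage recovered from the lists was 21.3% lower in hypoxia, and after thinning to equal background the hypoxia lists held 25.5% fewer peaks. Lists shared more bases within than between oxygen levels: the mean Jaccard index was 0.658 within and 0.527 between (exact permutation p = 0.1, n = 3, and 0.2 without normoxia replicate 3). This holds for the means only: hypoxia replicate 3 had an index of 0.617, 0.613 and 0.593 with the normoxia lists and 0.585 with hypoxia replicate 2.

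**Figure D2:**
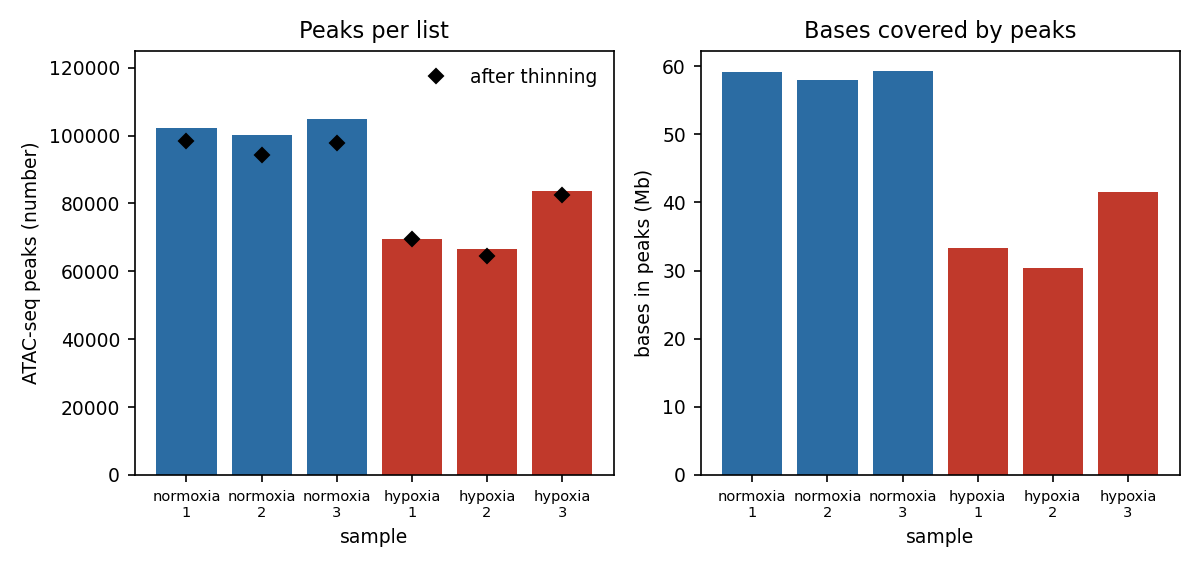
ATAC-seq peaks per list (left, bars; diamonds after thinning to the lowest background coverage) and megabases covered by peaks (right) for the 3 normoxia (blue) and 3 hypoxia (red) samples. Every hypoxia list lies below every normoxia list on both measures.

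Regions open in normoxia alone far outnumbered regions open in hypoxia alone. Of 136122 regions, 45364 were open in all 6 lists, 8815 were normoxia-specific and 46 hypoxia-specific. Among hypoxia-specific regions, the largest minimum fold belonged to chromosome 21, 14956624 to 14957268, near NRIP1, followed by chromosome 11, 28792634 to 28793348, chromosome 10, 38578910 to 38579147, chromosome 9, 104907196 to 104907623, within ABCA1, and chromosome 5, 170312702 to 170313084. Normoxia-specific regions with a large minimum fold included chromosome 7, 81483958 to 81484831, chromosome 18, 56043633 to 56044485, chromosome X, 119669179 to 119669992, within SEPTIN6, and chromosome 8, 11943659 to 11944114. With the 50000 strongest peaks of each list, 1412 regions were normoxia-specific and 509 hypoxia-specific. The hypoxia-specific count rose to 243 without hypoxia replicate 3, 199 without hypoxia replicate 2, 186 without hypoxia replicate 1, and 94, 75 and 87 without normoxia replicates 1, 2 and 3, and the normoxia-specific count rose to 16810 without hypoxia replicate 3.

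Specific regions lay less often near gene ends than regions open in all lists, except hypoxia-specific regions with trimmed peaks. Of regions open in all lists, 26.4% (95% interval 26.0 to 26.8) lay within 1 kb of the end of a gene span. Of normoxia-specific regions 10.3% (9.68 to 11) did (Fisher's exact p = 2.34e-268). Of hypoxia-specific regions 1 of 46 did, 2.17% (0.055 to 11.5, Fisher's exact p = 2.8e-05). Regions are not replicates, so both p-values cover the regions of these lists only. The classes were not matched for peak strength. The share of hypoxia-specific regions was 6.03% without hypoxia replicate 2, 5.35% without hypoxia replicate 3, 1.33% without normoxia replicate 2, 9.26% (5 of 54) after thinning and 8.7% within 2.5 kb, where regions open in all lists had 30.8%. With trimmed peaks the share of hypoxia-specific regions was 45.9% against 17.7%, the opposite direction, while that of normoxia-specific regions was 10.8%.

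At EPAS1 (chromosome 2, 46297407 to 46386697), no region was specific to either oxygen level. Within 50 kb of the gene lay 26 regions, of which 9 were open in all 6 lists, 17 in more normoxia than hypoxia lists and 0 in more hypoxia lists. Over all 136122 regions, 73151 (53.7%) were open in more normoxia lists and 12304 (9.04%) in more hypoxia lists, against 65.4% in more normoxia lists at EPAS1, a difference that was not tested. Regions open in all lists include 46296458 to 46300095, which spans a gene end, and 46314650 to 46315875, 46334800 to 46336501 and 46351413 to 46353037 inside the gene. The regions at 46350321 to 46350723, inside the gene, and at 46248213 to 46248503 and 46253169 to 46253532, outside it, were open in 3 normoxia lists and 1 hypoxia list. Across 44 genes of the core hypoxia and HIF pathway lists, 259 of 563 regions (46%) were open in more normoxia lists and 36 (6.39%) in more hypoxia lists, and the only hypoxia-specific region lay at NDRG1, a core hypoxia gene. With the same number of peaks per list, a region inside EGLN3 (chromosome 14, 33938271 to 33939041) was hypoxia-specific too. EGLN3 had 3 regions open in more hypoxia lists and 1 in more normoxia lists.

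**Figure D3:**
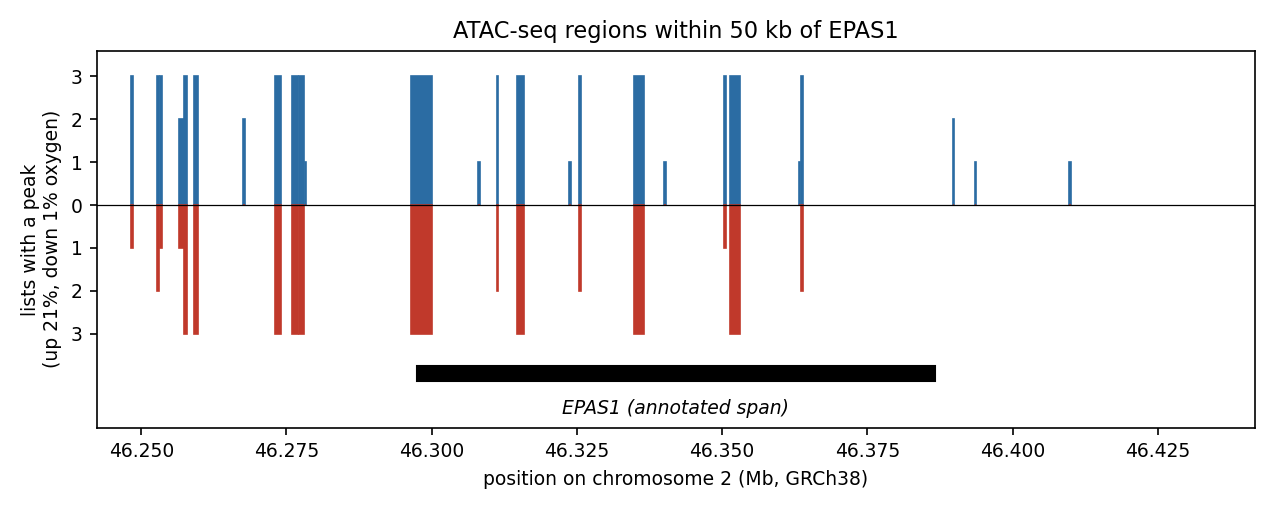
Regions within 50 kb of EPAS1 on chromosome 2 (Mb, GRCh38), with the number of normoxia lists (blue, up) and hypoxia lists (red, down) that hold a peak; the black bar is the annotated gene span. In 9 of 26 regions all 6 lists hold a peak, and none is held by more hypoxia than normoxia lists.

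Of 29 genes nearest to hypoxia-specific regions, 15 rose and 7 fell, and whether they passed as a set depended on the test and on 1 list. Their values include NEDD9, a focal adhesion scaffold, at a log2 fold change of 2.03, EPB41L3 at 1.39, NDRG1 at 1.23, NRIP1, a nuclear receptor corepressor, at 0.84, and NOLC1 at -0.63. The camera p was 0.00132, with p = 0.131 at an estimated correlation, and the odds ratio of rise over fall against other genes was 2.14 (95% interval 0.819 to 6.2, Fisher's exact p = 0.133). The camera p was 0.331 without hypoxia replicate 3 and 0.108 with trimmed peaks. With the same number of peaks per list, 142 of 325 genes nearest to hypoxia-specific regions rose and 96 fell. Their odds ratio was 1.49 (95% interval 1.14 to 1.95, Fisher's exact p = 0.00307). The camera p of these 325 genes was 0.00172, and 0.0594 at an estimated correlation. With all peaks but without hypoxia replicate 3, 124 genes were nearest, and their odds ratio was 1.14 (95% interval 0.736 to 1.77). Leaving out any other list gave odds ratios of 1.5 to 2.92. The set with the same number of peaks was not tested without single lists. Of 4570 genes nearest to normoxia-specific regions, 1628 rose and 1515 fell (camera p = 0.49; odds ratio 1.11, 95% interval 1.02 to 1.21, Fisher's exact p = 0.0205). With the same number of peaks per list that odds ratio was 0.972 (95% interval 0.834 to 1.13). For the 12304 genes nearest to regions open in all lists it was 1.13 (95% interval 0.997 to 1.28). The value of 1.11 thus does not set normoxia-specific regions apart from other open regions. Genes are not independent replicates in these tests, and NEDD9, EPB41L3, NDRG1, NRIP1 and NOLC1 were chosen after their values were seen.

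**Figure D4:**
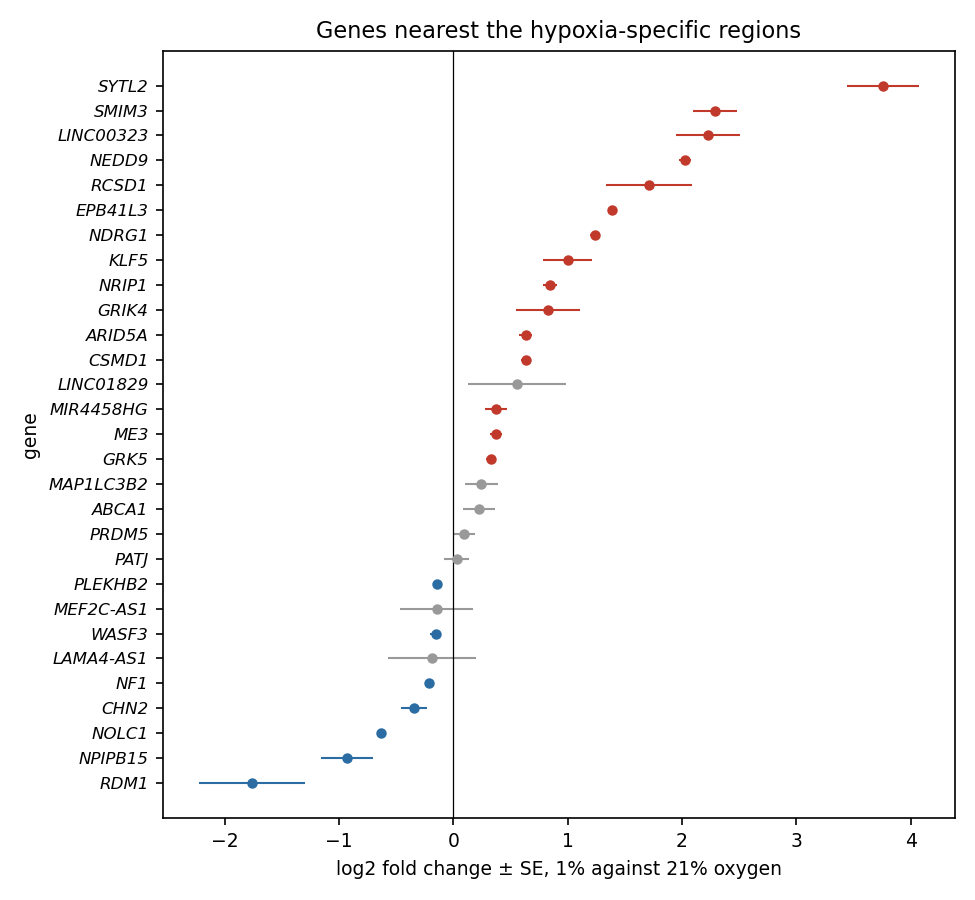
Log2 fold change ± SE (1% against 21% oxygen, 3 libraries each) of the 29 genes nearest to hypoxia-specific regions: red rose, blue fell, grey did not pass. Of the 29, 15 rose and 7 fell.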

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

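Thinning to equal background, the estimated correlation for genes near regions, and the occupancy of at least 2 lists for location and nearby genes were chosen after seeing the data. Of 16332 genes, 10110 changed with TMM, and the count stayed within 1.5 times under every setting except glmTreat, which tests for a fold beyond 2 and left 402. The percent of changed genes that were higher, 50 with TMM, was 51.0 with DESeq2, 48.2 with upper-quartile factors, 19.9 with library size, 17.6 on log2(TPM + 1), 17.4 on log2(TPM + 0.1) and 48.8 to 50.9 in leave-one-out. Of 111 named genes, 100 kept direction and call in each of the 17 settings that tested them. FAP, EGR3, PDGFRB and CSF3 were not tested with a CPM of at least 1. KRT18 reversed to -0.11 with library size and to -0.13 on both TPM scales, and CD68 to -0.04 on log2(TPM + 1) and -0.05 on log2(TPM + 0.1). Across list settings, 369 results kept direction and side of the threshold, 43 became weaker, 19 stronger and 23 reversed. List values below are camera adjusted p unless fry is named. With an estimated correlation glycolysis and core hypoxia passed, and the HIF pathway had 0.569, collagen modification 0.221, matrix 0.713, angiogenesis 0.221, cell cycle 0.713, cholesterol 0.783, interferon 0.783, TGF-beta 0.293 and autophagy 0.722. With DESeq2 cholesterol had 0.0693, and endothelial identity (0.884) and TCA cycle (0.866) reversed. With limma-voom the HIF pathway had 0.331, angiogenesis 0.311, interferon 0.0737, TGF-beta 0.0554 and OXPHOS 0.0121, and endothelial identity (0.926), ER stress (0.941), immediate early (0.743) and smooth muscle (0.635) reversed. With RLE TCA cycle reversed (0.987), and with upper-quartile factors autophagy had 0.059. With library size the HIF pathway had 0.071, matrix 0.303, endothelial identity 0.0415, inflammation 0.016, interferon 0.101, p53 targets 0.0415 and autophagy 0.493, and OXPHOS (0.773), pericyte (0.998) and epithelial (0.908) reversed. Without a filter OXPHOS had 0.0146 and inflammation 0.0085, and TCA cycle reversed (0.816). With a CPM of at least 1 cholesterol had 0.0627 and autophagy 0.0893. On log2(TPM + 1) the HIF pathway had 0.369, matrix 0.341, inflammation 0.0128, interferon 0.294 and autophagy 0.395, and ER stress (0.954) and OXPHOS (0.615) reversed. On log2(TPM + 0.1) the same lists had 0.365, 0.359, 0.0134, 0.319 and 0.39, and ER stress (0.95) and OXPHOS (0.598) reversed. With counts scaled from TPM cholesterol had 0.064, interferon 0.0571 and autophagy 0.0559, and TCA cycle reversed (0.965). With a replicate block, though the numbers do not pair samples, cholesterol had 0.0563 and inflammation 0.0487, and TCA cycle reversed (0.984). With fry, adjusted p was 0.0224 for dioxygenases, 0.00227 for OXPHOS, 0.0224 for inflammation, 0.000159 for p53 targets, 0.00322 for immediate early genes, 0.00732 for smooth muscle, 0.0243 for fibroblast, 0.0224 for epithelial and 0.000867 for lymphatic markers, and ER stress (0.959) and TCA cycle (0.187) reversed. In leave-one-out the ranges were 0.00512 to 0.051 for matrix, 0.0353 to 0.0962 for cholesterol, 0.0191 to 0.091 for interferon, 0.0189 to 0.0602 for autophagy, 0.00509 to 0.149 for inflammation, 0.626 to 0.903 for ER stress and 0.809 to 0.991 for TCA cycle. Genes with changed isoform usage, 362, numbered 214 with transcripts of at least 10%, 1037 with the F test and 211 with the replicate block. Hypoxia-specific regions, 46, numbered 24 and 13 at -log10 q of at least 5 and 10, 509 with the same number of peaks per list, 2358 with trimmed peaks, 537 in at least 2 lists and 75 to 243 in leave-one-out. Normoxia-specific regions, 8815, numbered 1412 with the same number of peaks, 18408 in at least 2 lists and 9839 to 16810 in leave-one-out. Leaving out a list or asking for 2 lists loosens the condition by construction. Of the 2358 trimmed regions, 98.4% were touched by an untrimmed normoxia peak, so trimming itself made most of them, and their share near gene ends reversed to 45.9%. The camera p of genes near hypoxia-specific regions, 0.00132, was 0.131 with an estimated correlation, 0.108 with trimmed peaks and 1.41e-06 to 0.331 in leave-one-out. At EPAS1, 10 regions within 10 kb were open in more normoxia lists. The peak counts kept their direction in every setting, but with 3 lists against 3 no permutation p can fall under 0.1. For changes other than those explained by construction, the cause was not tested. Motif counts and distances to transcription starts were not run. On counts simulated with the depth and spread of these libraries, 66% of genes at a fold of 1.5 were recovered. The simulation changed 200 genes with 16042 tested, against 10110 of 16332 in the data. Adjusted p depends on how many genes change, so the 66% does not give the recovery in the data. What depth alone limits was not tested.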

Other observations

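The tests of depth, number of calls, median fold, nearest genes, the genes that gained most counts, RNA content, smooth muscle and fibroblast markers, and the other splits of the samples were chosen after the results they concern were seen, and so were their bounds. The bound of the gene length test was written before its value was computed.

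The hypoxia ATAC lists held fewer peaks, and normoxia-specific regions outnumbered hypoxia-specific ones 192 to 1, a ratio that was 129, 163 and 145 without normoxia replicates 1, 2 and 3, 55.7, 49.4 and 69.2 without hypoxia replicates 1, 2 and 3, and 376 and 721 at -log10 q of at least 5 and 10. The ratio was 142 after thinning, 34.3 for regions open in at least 2 lists and 3.62 with trimmed peaks. After thinning to equal background coverage, hypoxia lists held 25.5% fewer peaks, and each was shorter than each normoxia list. Thinning redrew only the summit pileups of peaks already called and did not call peaks anew, so it can understate what depth removes. Lower sequencing depth thus did not level the lists in this form, but it stays open. Closing of chromatin that lowers the nearest genes stays open. Their odds ratio of rise over fall was 1.11 (95% interval 1.02 to 1.21), near the 1.13 (0.997 to 1.28) of genes nearest to regions open in all lists. It was 0.972 (0.834 to 1.13) with the same number of peaks per list. With that same number the ratio of normoxia-specific to hypoxia-specific regions was 2.77, against at most 2.62 in the other splits of the samples. Giving every list the same number of peaks draws this ratio toward 1 by construction, so it cannot tell where the imbalance comes from. At the 45364 regions open in all 6 lists the median fold was 6.75, 6.01 and 7.73 in hypoxia and 9.13, 8.62 and 8.65 in normoxia (exact permutation p = 0.1, the smallest possible), but the fold also depends on background coverage, so a lower share of reads in peaks and a wider loss of accessibility at 1% oxygen both stay open.

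Abundant genes were higher in hypoxia with TMM, with a median log2 fold change of 0.206 in the most abundant decile. Those of the cytosolic ribosome were higher with either scaling. With library-size scaling the median over all genes was -0.272, a shift of -0.264 from TMM, which is larger in size than 0.206. The 10 genes that gained most counts are argued against as the whole source, since the median was still -0.204 without them. It was -0.13 without the 100 that gained most, -0.0497 without 500 and -0.024 without 1000, but leaving out genes chosen for their gain moves the median toward 0 by construction, so these values decide nothing. Gene length stays open: in the most abundant decile the median log2 fold change was 0.30 in the shortest length tertile, 0.20 in the middle one and 0.0899 in the longest, a value between the bounds written beforehand. The shift of -0.264 is the gap between TMM and library-size scaling of the same counts. A change in RNA content per cell that is equal for all genes cancels in both scalings and cannot give it. Which scaling is nearer the amounts per cell stays open, since no RNA of known amount was used here.

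TAGLN, CCN2, TGFB2 and CDH2, which mesenchymal cells express, were higher in hypoxia. Smooth muscle cells in the hypoxia cultures as the source of this rise are argued against by ACTA2, at a log2 fold change of -0.48, and by SMTN, at -0.52. Both were present in normoxia, at 21.6 and 146 CPM with library-size scaling, so their fall cannot exclude a small number of such cells. Fibroblasts are argued against by the summed CPM of COL1A1, COL3A1, DCN and LUM, abundant transcripts of these cells, which with library-size scaling was 0.604 in normoxia and 0.474 in hypoxia, a ratio of 0.786 (0.942 with TMM), while CDH2 gained 104 CPM on the same scale. Of 10 fibroblast markers 6 were lower by value in hypoxia and 3 higher with either scaling, DCN (0.0744 to 0.221 CPM with TMM), FAP (0.418 to 0.787) and COL1A2 (53.5 to 74.9). A response of the endothelial cells to 1% oxygen also stays open and was not tested.

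The 6 libraries of each assay can be split in 10 ways, too few for a share under 0.05. The real split gave 10110 changed genes, and the highest of the others 0. For isoform usage these counts were 362 and 95, and for condition-specific regions 8861 and 1413. In each case 1 of the 10 splits, the real one, reached the real count.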
